A study of Homo sapiens with 4 samples.

How the data were processed

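RNA was measured by droplet single-cell sequencing of transcript 3′ ends, with the 10x Chromium kit per the labels, in H9 human embryonic stem cells. There were 4 libraries: wild type and SIRT1 knockout, each at day 0 and at day 6 of differentiation towards dopaminergic neurons. Groups were taken from the labels of genotype and day, with 1 library in each. Per the labels, cells were grown on Geltrex in mTeSR1 medium and detached with TrypLE. Whether the wild-type and knockout cultures were handled in parallel is not given in the sources used here.

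The deposited values were raw UMI counts per gene and barcode, not normalised, for 36601 features. Per the submitters' processing notes, reads were processed with Cell Ranger 6.1.2 against GRCh38, while the header of the deposited count matrices names Cell Ranger 4. The version of the gene annotation is not given in the sources used here. The deposited counts held every barcode, from 1556315 to 1881372 per library, so cells were called here. The 4 libraries held 78774434 (wild type, day 0), 78917192 (knockout, day 0), 54824132 (wild type, day 6) and 68523677 (knockout, day 6) UMIs.

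A barcode was called a cell where its total reached 1/10 of the 99th percentile of the highest totals, a rule that gave limits of 2723, 3556, 2340 and 3829 UMIs in that order. Cells with fewer than 1000 genes (14 in all, in wild type at day 6) or more than 20% mitochondrial UMIs (7, 3, 2 and 0 cells) were left out. Doublets were kept. Scrublet's automatic threshold marked under 0.5% of the cells of each library, which was treated here as a call that had not worked, so an alternative removed the highest scores at 0.8% per 1000 cells. Medians of mitochondrial UMIs per cell were 5.42%, 4.81%, 1.99% and 1.61%. Ribosomal protein genes held 22.7%, 23.3%, 30.3% and 26.2% of the UMIs in cells, a share that enters every level scaled to the total. A profile of free RNA came from barcodes with 1 to 50 UMIs.

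Counts were summed over the cells of a library and given as counts per 1000000 UMIs (CPM). Cells are not replicates, so with 1 library per group no test was run and no p-value is given. For each of 4 comparisons (knockout against wild type at each day, and day 6 against day 0 in each genotype) the ratio of CPM was given with its exact conditional binomial (Clopper-Pearson) 95% interval. These intervals compare the libraries, not the conditions, and cover counting error only. A gene was measured where it reached 10 CPM in 1 of the 2 libraries. The size rule asked for a ratio of at least 2-fold with an interval excluding 1, and for list members at least 1.5-fold. Log2 ratios used a prior count of 0.5, and a count of 0 was given a floor of 3 counts. The difference between days is the log2 ratio at day 6 minus that at day 0.

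Named genes were the 10 highest and 10 lowest log2 ratios of each comparison among genes at 20 CPM or more, and the 5 highest and 5 lowest for the difference between days. Ribosomal protein, mitochondrially encoded and sex-linked marker genes and clone-style or LINC names were left out of that ranking. To these came SIRT1 and up to 4 members with the largest ratios from each of 47 gene lists. The lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. Some genes that meet the rule are not reported here. Each list was described by its members past 1.5-fold, its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. A gene can stand in more than 1 list. Near-identical gene copies share reads that the counting could split, and their counts are uncertain.

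Shares of cells with a UMI and cell-cycle phases were computed on cells thinned to 5000 UMIs each. The share that free RNA would give assumed 10% of a cell's UMIs. Each library was clustered by itself after scaling to 10000 counts per cell and log transformation, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. Cluster borders moved with the numerical precision of the components, which was double here, so cluster sizes are approximate. A cluster was called by a cell type's name only where at least 3 markers of a fixed list were at least 2-fold higher than in the other cells. That class also had to have the most such markers by itself, and a marker among the cluster's 10 leading genes. The exception was a class found in the whole library, whose markers had to be detected in 50% of its cells. Gene positions came from the GENCODE annotation of GRCh38 and were joined by Ensembl identifier. The deviation of a chromosome is the median log2 ratio of its measured genes minus that of all genes, with a bootstrap interval over genes from 10000 draws. The chromosome 20 share of a cell left out ribosomal protein and mitochondrially encoded genes, and its limits of 2.6% and 3% were set after the shares had been seen. Choosing cells by this share moves the levels of chromosome 20 genes by construction.

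Alternatives changed 1 choice at a time: the limit on UMIs, the mitochondrial filter, doublets, equal weight for every cell, subtraction of the free RNA profile, the scaling (TMM factors, median-of-ratios factors, totals without mitochondrial and ribosomal protein genes), the minimum CPM, the fold of the size rule, the prior count, thinning and the Leiden resolution. At day 0 the pluripotent-like clusters were also compared alone. The alternatives based on chromosome 20, and the counts of list members under alternatives, were chosen after seeing the data. The ratio, interval and list code was tested on simulated data drawn from the real library sizes. The simulated libraries shared a profile and differed only by counting error and the set folds. They therefore check the code and say nothing about spread between cells or cultures. In the simulated day 0 comparison of knockout and wild type, run on 8935 genes, 100% of 50 genes at a true fold of 2.5 and 98% of 50 at 4 passed the size rule, and no unchanged gene did. In that of day 6, run on 7910 genes, both shares were 100%, and so they were in the simulated comparisons of days in wild type (8966 genes) and knockout (8882 genes). Genes at a true fold of 1.3 or 1.7 passed in 0% of cases in each of the 4. Intervals held the true ratio for 95.2% of unchanged genes at day 0 and 95.0% at day 6.

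The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5 (whose Scrublet port was used), leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3 for the TMM factors only.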

Results

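The data came from H9, a human embryonic stem cell line, profiled by droplet single-cell RNA sequencing of transcript 3′ ends, in which a unique molecular identifier (UMI) counts each captured RNA molecule once. Wild-type cells and cells of a SIRT1 knockout were profiled at day 0, as undifferentiated cells, and at day 6 of a protocol towards dopaminergic neurons. SIRT1 is an NAD-dependent protein deacetylase, and the series asks how it bears on metabolism and differentiation of human stem cells. There were 4 libraries, 1 per group, so none of the differences has a replicate check and no test between conditions was made. After filtering, 5651 wild-type and 7384 knockout cells remained at day 0, with medians of 12504 and 8309 UMIs per cell. At day 6, 5580 wild-type and 4429 knockout cells remained, with medians of 8431 and 13154 UMIs. The summed cells held 73807477 and 73865043 UMIs at day 0 and 52116199 and 65375797 at day 6, wild type first. Levels are counts per 1000000 UMIs (CPM) of the summed cells. The range in parentheses after a ratio, a level or a share is its exact 95% interval, which covers counting error only.

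SIRT1 (ENSG00000096717), the targeted gene, lies on chromosome 10 from 67884669 to 67918390 on the plus strand of GRCh38, the build of all positions given here. Its level was 32.3 CPM (31.0 to 33.6) in wild type and 7.12 CPM (6.53 to 7.76) in the knockout at day 0. At day 6 it was 30.3 CPM (28.8 to 31.8) and 9.96 CPM (9.21 to 10.8). The knockout was thus 4.54-fold (4.13 to 4.99) lower at day 0 and 3.04-fold (2.77 to 3.33) lower at day 6. With every cell thinned to 5000 UMIs, a SIRT1 UMI was found in 14.2% (13.3 to 15.2) of wild-type and 3.61% (3.18 to 4.08) of knockout cells at day 0, and in 12.7% (11.8 to 13.6) and 5.28% (4.63 to 5.98) at day 6. Without thinning these shares were 32.1%, 6.84%, 22.6% and 13.0%. Free RNA at 10% of a cell's UMIs would give thinned shares of 0.792% and 0.527% in the knockout libraries. SIRT1 was thus lower in both knockout libraries, the direction that the genotype labels give. The labels give no account of which part of the gene was deleted, so the remaining 3′ tags do not show whether a working transcript was left.

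**Figure D1:**
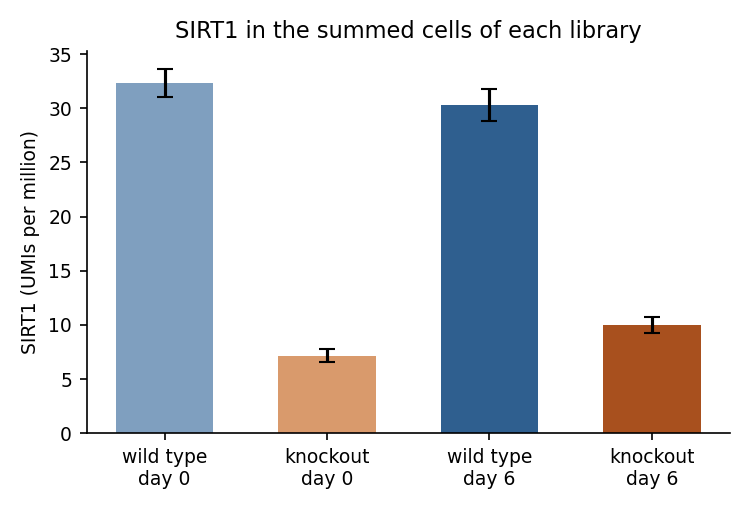
SIRT1 level in CPM (vertical axis) in the summed cells of the 4 libraries, with exact 95% Poisson intervals as error bars. The knockout libraries stand at 7.12 and 9.96, the wild-type libraries at 32.3 and 30.3.

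The comparison at day 0 asks what the knockout does in undifferentiated cells. Knockout cells held more RNA of most measured hypoxia-response genes and of some glycolysis and cholesterol-synthesis genes than wild type. They held less of 3 pluripotency-associated and 3 mitochondrially encoded genes. Of the hypoxia-response list, 9 of 13 measured members were higher, 0 lower and 4 neither, and of the glycolysis list 8 of 24 measured members were higher, 0 lower and 16 neither. Among genes at 20 CPM or more in 1 of the 2 libraries, the range that also holds for the rankings that follow, the highest ratio belonged to APLN, the gene of the peptide ligand apelin (chromosome X, 129645259 to 129654937), at 5.15-fold (4.67 to 5.69), and the lowest to MT1H, a metallothionein gene (chromosome 16, 56669814 to 56671129), which was 18.4-fold (15.2 to 22.5) lower. Below that range S100A6 stood at 17.3 CPM in wild type and 0.474 CPM in the knockout, 36.5-fold (26.1 to 52.7) lower, and was named after its values were seen. The metallothionein genes are near-identical copies, so their counts are uncertain. Of 9093 genes at 10 CPM or more in 1 of the 2 libraries, 40 were at least 2-fold higher and 43 at least 2-fold lower with an interval excluding 1. The median log2 ratio of all measured genes was -0.01.

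Among the 10 highest ratios at day 0, SORBS2, a cytoskeletal adaptor, was 4.70-fold (4.42 to 5.01) higher in the knockout, and SLC16A3, the lactate exporter MCT4, 3.55-fold (3.34 to 3.77). EDNRB, an endothelin receptor, followed at 3.21-fold (2.96 to 3.49) and PFKFB4, which makes and breaks down the glycolytic activator fructose 2,6-bisphosphate, at 3.01-fold (2.74 to 3.31). TMEM88 was 2.74-fold higher, INSIG2, which holds sterol sensors in the endoplasmic reticulum, 2.62-fold, the glycoprotein hormone STC1 2.54-fold and ID2, an inhibitor of basic helix-loop-helix factors, 2.44-fold. Fibronectin (FN1) was 2.81-fold (2.63 to 3.01) higher over all cells, but its log2 ratio of 1.49 became 0.27 when only pluripotent-like clusters were summed, which left out, among others, a knockout cluster with FN1 and COL1A1 as its leading genes. SORBS2 had a log2 ratio of 2.23 over all cells and 1.48 in the knockout cells with 3% or more of their UMIs from chromosome 20, a share like that of wild type.

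Below MT1H and SIRT1, the lowest ratios at day 0 among genes at 20 CPM or more belonged to SLFN13, a schlafen family member (3.08-fold lower), VSNL1, a neuronal calcium sensor (3.07-fold), the metallothionein MT1G (3.04-fold) and the antisense RNA ZNF433-AS1 (2.57-fold). THEM4, a thioesterase, was 2.35-fold lower, DNAJC15, a mitochondrial co-chaperone, 2.30-fold, ID1 2.29-fold and the tight junction gene CLDN7 2.24-fold. ID1 lies on chromosome 20, whose genes as a set were lower in the knockout. In the class of knockout cells with a chromosome 20 share like wild type, the log2 ratio was -0.56 for ID1 against -1.19 over all cells, -0.29 against -1.16 for CLDN7, -0.31 against -1.36 for ZNF433-AS1 and -2.93 against -1.62 for SLFN13. For ID1, part of this change comes with choosing cells by that share.

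The hypoxia-response list had a median log2 ratio of 0.69 at day 0, at percentile 100 of 10000 random lists matched on expression. Its members ANKRD37 (2.57-fold), the mitophagy receptor BNIP3 (2.27-fold), the prolyl hydroxylase EGLN1 (2.16-fold) and FAM162A (1.99-fold) had the largest ratios, all higher. In the glycolysis list, median 0.47 at percentile 100, the phosphoglycerate kinase gene PGK1 was 1.85-fold and hexokinase HK2 1.79-fold higher. Of the cholesterol-synthesis list, 7 of 21 measured members were higher, 0 lower and 14 neither, with a median of 0.46 at percentile 100. Its larger ratios included those of INSIG1 (2.14-fold), HMGCS1 (1.85-fold) and STARD4 (1.76-fold). In knockout cells with a chromosome 20 share like wild type, 2 of 21 were higher and the median was 0.32. In the fatty acid synthesis list, 0 of 12 measured members were higher, 1 lower and 11 neither, the median being 0.28 at percentile 99.99, with FASN at 1.40-fold and SCD at 1.37-fold, short of 1.5-fold. For p53 target genes, 3 of 21 measured members were higher, 0 lower and 18 neither, the median being 0.29 at percentile 100, and 5 were higher in knockout cells with a chromosome 20 share like wild type. The higher members over all cells were the antiproliferative gene BTG2 (1.55-fold), ZMAT3 (1.51-fold) and SESN1 (1.51-fold).

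In the pluripotency list, 0 of 17 measured members were higher, 3 lower and 14 neither, with a median of -0.20 at percentile 0.03. The median was -0.12 at percentile 2.01 in knockout cells with a chromosome 20 share like wild type, and -0.12 at 0.915 without chromosome 20 genes. The lower members were the de novo DNA methyltransferase DNMT3B (1.88-fold lower, on chromosome 20), L1TD1 (1.54-fold) and the NODAL co-receptor TDGF1 (1.52-fold). POU5F1 had a ratio of 1.09 and NANOG of 0.870. Of the mitochondrially encoded respiratory genes, 0 of 13 measured members were higher, 3 lower and 10 neither, median -0.28 at percentile 0, with MT-ATP8 1.72-fold and MT-ND3 1.66-fold lower. Of the nuclear genes of oxidative phosphorylation, 0 of 75 measured members were higher, 1 lower and 74 neither, with a median of -0.01. Of the integrated stress response list, 0 of 14 measured members were higher, 3 lower and 11 neither, among them TRIB3 (1.78-fold lower), CEBPB (1.69-fold) and DDIT3 (1.55-fold). TRIB3 and CEBPB lie on chromosome 20, and in knockout cells with a chromosome 20 share like wild type the log2 ratio of TRIB3 was 0.023 and the list median 0.10, against -0.22 over all cells. Choosing cells by that share raises genes of chromosome 20 by construction, and these enter the list median. The S phase list had 0 higher, 0 lower and 39 neither of 39 members and a median of -0.13 at percentile 0.02, and the G2 and M phase list 0 higher, 0 lower and 52 neither of 52 and -0.03.

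At day 6 the knockout library held more RNA of several cell-cycle genes and of GBX2 and FABP7 than wild type, and less of several p53 target, immediate early and adhesion genes. GBX2, a homeobox gene of the midbrain-hindbrain region (chromosome 2, 236165236 to 236168369), was 6.57-fold (5.85 to 7.41) higher, and FABP7, the fatty acid binding protein of neural progenitors, 5.96-fold (5.59 to 6.36). S100A6, the gene of a calcium-binding protein (chromosome 1, 153534599 to 153536244), was 21.1-fold (18.3 to 24.5) lower. Of 8726 measured genes, 270 were higher and 173 lower by the size rule. The split differed with the scaling. Scaled to total UMIs, 60.9% of these genes were higher, against 26.1% with TMM factors (100 higher, 283 lower). The median log2 ratio of all measured genes was 0.25, and 0.01 with TMM factors, so list medians at day 6 are given relative to that of all genes.

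Of the other high ratios at day 6, the sialyltransferase gene ST6GALNAC5 was 5.05-fold higher, the transcription factors NFE2L3 and SOX5 4.93-fold and 4.79-fold, and the growth factor pleiotrophin (PTN) 4.22-fold (4.13 to 4.31), at 755 CPM against 179. PPP3CA, a catalytic subunit of calcineurin, was 4.20-fold higher, the neuropeptide precursor NTS 4.15-fold, the neuroligin NLGN4X 3.79-fold and TAGLN3 3.48-fold. Several of these ratios were smaller in the knockout cells with a chromosome 20 share like wild type, where the log2 ratio was 1.48 for FABP7 against 2.57 over all cells, 0.88 against 2.08 for PTN and 0.56 against 2.05 for NTS. The same held for SOX5 (1.43 against 2.26), PPP3CA (1.08 against 2.07), NLGN4X (1.21 against 1.92) and TAGLN3 (1.11 against 1.80). The classes also differed in their clusters. Of the cells of an unnamed knockout cluster with PTN, NEFM and FABP7 among its leading genes, 84.1% had a chromosome 20 share below 2.6% and 9.71% one of 3% or more, against 48.8% and 39.5% of a cluster with FN1 and FOXA2 among its leading genes. In wild type the share also differed with the cluster, since 12.2% of a cluster with PTN, NEFM and FABP7 among its leading genes and 1.25% of the larger one with FN1 and FOXA2 were below 2.6%. The lowest ratios included ANXA1, an annexin (17.5-fold lower), SPP1, which encodes osteopontin (17.2-fold), endothelin EDN1 (10.3-fold), the potassium channel genes KCNJ2 (9.27-fold) and KCNF1 (7.64-fold), ANKRD1 (7.79-fold), the actin-binding gene TAGLN (7.44-fold) and EMP1 (6.62-fold). In wild type at day 6, ANXA1, TAGLN and SPP1 were among the 10 leading genes of a cluster of 570 cells. The log2 ratio of S100A6 was -4.40, and -5.34 in the knockout cells with a chromosome 20 share like wild type. With the ambient profile subtracted, no counts of it were left in the knockout.

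Of the p53 targets at day 6, 1 of 22 measured members were higher, 8 lower and 13 neither, and the median lay -0.77 from that of all genes, at percentile 0 of random lists. The cyclin-dependent kinase inhibitor CDKN1A was 4.22-fold (4.08 to 4.37) lower, GDF15 3.50-fold, PLK2 2.67-fold and PHLDA3 2.09-fold. Of the apoptosis regulators, 2 of 12 measured members were higher, 4 lower and 6 neither, at -0.66 and percentile 0. Their lower members included BCL2L1 (2.74-fold, on chromosome 20), BBC3 (2.07-fold), which is also in the p53 list, and PMAIP1 (1.66-fold). In the list of immediate early and dissociation genes, 1 of 11 measured members were higher, 6 lower and 4 neither, at -1.09 and percentile 0, with IER3 4.89-fold and DUSP1 2.08-fold lower and EGR1 2.08-fold higher. Of the integrated stress response list, 0 of 12 measured members were higher, 5 lower and 7 neither, at -0.79 and percentile 0, with ATF5 3.61-fold, PPP1R15A 2.06-fold and ATF3 1.80-fold lower. Among the surface ectoderm and keratin genes, 0 of 5 measured members were higher, 4 lower and 1 neither, with KRT8 2.07-fold and KRT19 2.05-fold lower. Of the extracellular matrix and adhesion list, 4 of 21 measured members were higher, 7 lower and 10 neither, at -0.47 and percentile 0, with CCN1 4.44-fold and THBS1 4.39-fold lower. With TMM factors, lower members numbered 13 of the p53, 8 of the integrated stress response, 6 of the apoptosis and 9 of the matrix and adhesion list, and 2 of the last were higher. In knockout cells with a chromosome 20 share like wild type, 9 immediate early genes were lower and 0 higher, 1 of the surface ectoderm genes was lower, and 2 matrix and adhesion genes higher.

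Several cell-cycle genes stood higher. Of the S phase list, 20 of 37 measured members were higher, 0 lower and 17 neither, at 0.34 relative to all genes and percentile 100, led by BRIP1 (2.46-fold), ATAD2 (1.98-fold) and CHAF1B (1.94-fold). Of the G2 and M phase list, 18 of 52 measured members were higher, 1 lower and 33 neither, at 0.20 and percentile 100, with CENPE 2.69-fold and MKI67 2.09-fold higher. The hypoxia-response list held 6 higher, 1 lower and 7 neither of 14 measured members, at 0.24 and percentile 99.98, with EGLN1 2.20-fold and EGLN3 2.18-fold higher and NDRG1 1.51-fold lower. For cholesterol synthesis the counts were 5 higher, 0 lower and 17 neither of 22, at 0.25 and percentile 99.99, with IDI1 1.93-fold higher, and for glycolysis 5 higher, 0 lower and 19 neither of 24, at 0.05 and percentile 99.25, with PFKFB4 2.07-fold and PFKP 1.96-fold higher. In knockout cells with a chromosome 20 share like wild type, the median before subtraction was 0.33 (percentile 97.63) for cholesterol synthesis and 0.24 for glycolysis, with all genes at 0.25. The counts past 1.5-fold also depended on the scaling. With TMM factors, higher members numbered 8 of the S phase, 9 of the G2 and M phase, 3 of the hypoxia-response, 2 of the cholesterol and 2 of the glycolysis list, where 2 were then lower. Of the neural crest markers, 4 of 5 measured members were higher, 1 lower and 0 neither, with ERBB3 2.95-fold and SOX9 2.04-fold higher and NGFR 1.63-fold lower, and 2 were higher and 0 lower in knockout cells with a chromosome 20 share like wild type. Of the neural progenitor markers, 6 of 12 measured members were higher, 0 lower and 6 neither, at percentile 93.35, with FRZB 2.34-fold and SOX3 2.15-fold higher beside FABP7. The pluripotency list held 2 higher, 5 lower and 9 neither of 16 members, with UTF1 5.11-fold and NANOG 2.44-fold lower and L1TD1 2.45-fold higher.

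**Figure D2:**
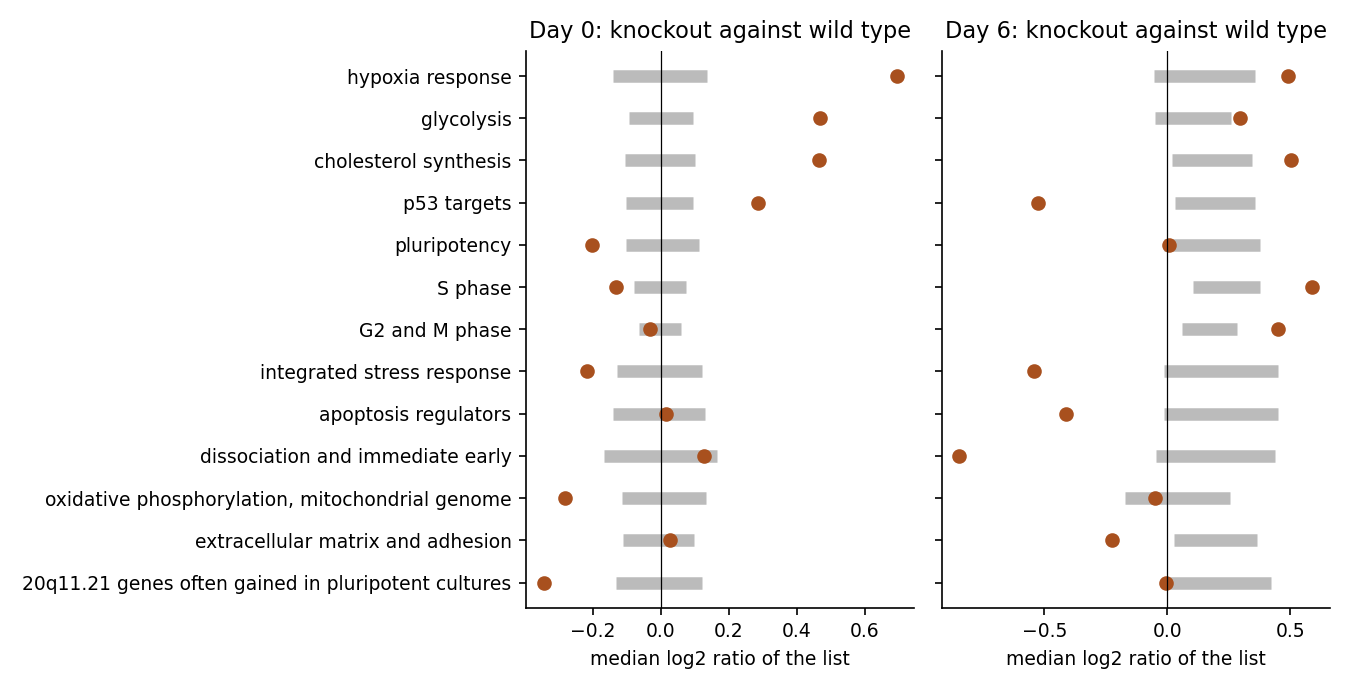
Median log2 ratio of knockout to wild type (horizontal axis, points) of 13 gene lists (vertical axis) at day 0 and day 6, with grey bars for the central 95% of medians of random lists matched on expression. The p53 targets lie at 0.29 at day 0 and -0.52 at day 6, and the hypoxia-response list at 0.69 and 0.49. Medians are drawn without subtracting that of all genes, which was -0.01 at day 0 and 0.25 at day 6.

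The knockout ratios of the 2 days were compared gene by gene. Across 8136 genes measured in both, the log2 ratios of day 0 and day 6 had Pearson's r of 0.232 and Spearman's rho of 0.0804, computed across genes, which are not independent replicates. In knockout cells with a chromosome 20 share like wild type, Pearson's r was 0.0892, against 0.226 in as many knockout cells drawn at random. A set of 10 genes was at least 2-fold higher at both days, where independent lists would share 0.840, and it included INSIG2, PFKFB4, STC1, EGLN1, the urea cycle gene CPS1 and LDOC1. Another 14 were lower at both days, against 0.328, including SIRT1, S100A6, ID1, SLFN13, ZNF433-AS1, the galanin gene GAL, TMBIM4 and STOM. A difference between the 2 lines other than SIRT1 itself, such as that of chromosome 20, could recur at both days. These overlaps are therefore no separate evidence of a SIRT1 effect. The ratio was at least 1 log2 unit more positive at day 6 for 291 genes and more negative for 109. This balance rested on the scaling, being 95 and 170 genes with TMM factors, and the median difference of all genes was 0.22 scaled to total UMIs and -0.015 with TMM. The most positive differences belonged to FABP7 (3.55), NFE2L3 (2.37), the neural RNA RMST (2.07), RBIS (2.03) and PPP3CA (2.03). The most negative belonged to SPP1 (-3.96), APLN (-3.70), the AP-1 member FOSL1 (-2.96), SORBS2 (-2.92) and FN1 (-2.88). None of these differences between days was tested.

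Genes of chromosome 20 were lower in both knockout libraries as a set. Over 247 measured genes, the median log2 ratio of chromosome 20 lay -0.31 from that of all genes at day 0 (bootstrap interval over genes -0.34 to -0.27) and -0.38 at day 6 (-0.42 to -0.33). The other 22 chromosomes lay between -0.04 and 0.08 at day 0, and between -0.18 and 0.11 at day 6. At day 0, 94.3% of chromosome 20 genes were below the median of all genes, and 84.2% at day 6. All 16 windows of 15 consecutive measured genes along the chromosome lay below 0 at both days. Of 20q11.21 genes often gained in pluripotent cultures, 0 of 15 measured members were higher, 2 lower and 13 neither at day 0, median -0.34, and 0 of 14 measured members were higher, 3 lower and 11 neither at day 6, among them ID1 (4.96-fold), BCL2L1 and PDRG1 (1.80-fold). Relative to all genes the median of that list at day 6 was -0.25 over all knockout cells and 0.13 in those with a chromosome 20 share like wild type. Before that subtraction it was -0.01, with all genes at 0.25, and 0.37, with all genes at 0.25. Choosing cells by a high chromosome 20 share raises a list of chromosome 20 genes by construction, so this rise is no separate result.

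**Figure D3:**
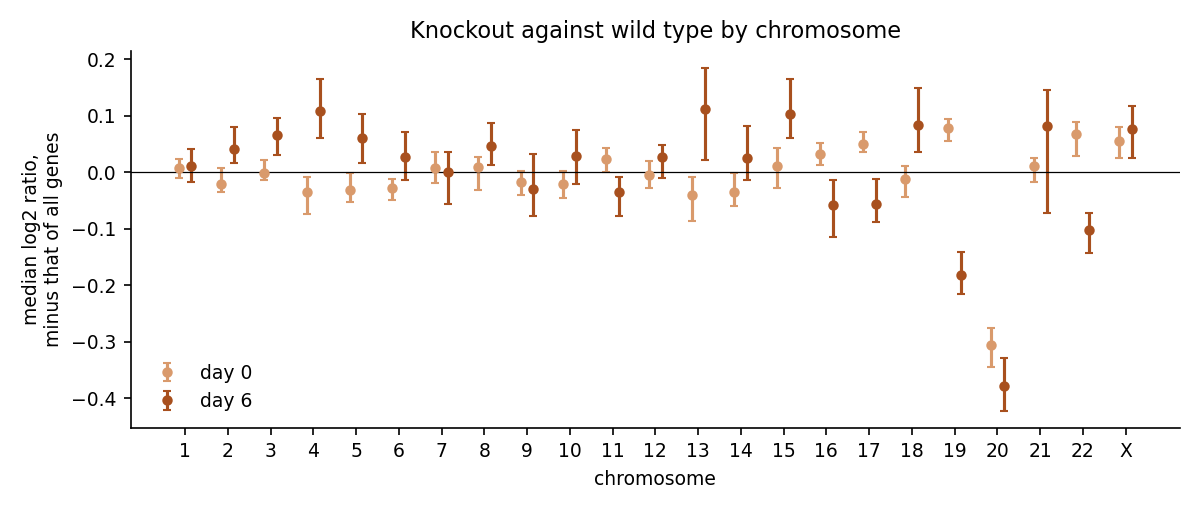
Median log2 ratio of knockout to wild type of each chromosome's measured genes minus that of all genes (vertical axis), by chromosome (horizontal axis), at day 0 and day 6, with bootstrap 95% intervals over genes. Chromosome 20 lies at -0.31 and -0.38, below every other chromosome at both days.

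Within the knockout libraries the share of chromosome 20 RNA differed between cells. The share of chromosome 20 among a cell's UMIs outside ribosomal protein and mitochondrially encoded genes had its main peak in wild type above 3%, with medians of 3.45% at day 0 and 3.25% at day 6. The knockout libraries had a peak on either side of a trough. At day 0, 56.2% of knockout cells (4150 cells) were below 2.6%, 28.5% (2102 cells) at 3% or more and 15.3% between. At day 6 these were 62.5% (2769 cells), 27.3% (1211 cells) and 10.1%. In wild type 0.655% and 3.67% of cells were below 2.6%, and the 37 such cells at day 0, with a median share of 2.39%, formed a small peak of their own. The limits were set after the shares were seen. SIRT1 was low in both classes of knockout cells, with a ratio to wild type at day 0 of 0.217 in cells below 2.6% and 0.243 in cells at 3% or more, and at day 6 of 0.326 and 0.310. Genes at least 2-fold apart between the classes at both days included ZNF433-AS1 and CST1 (on chromosome 20), higher in the cells with 3% or more, and NFIA, APELA, SORBS2, ITPR2 and NTS, lower in them, all named after their values were seen.

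**Figure D4:**
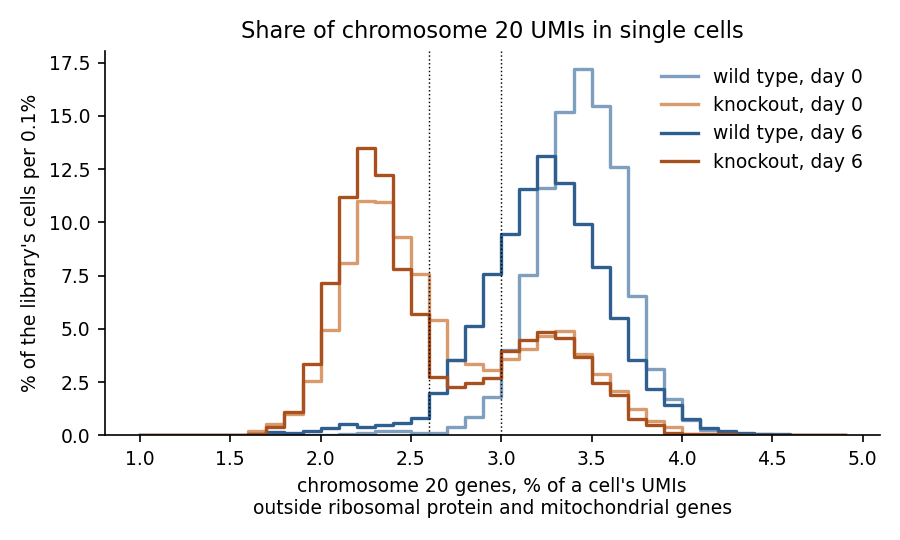
Percentage of a library's cells (vertical axis) by the chromosome 20 share of their UMIs in bins of 0.1% (horizontal axis), for the 4 libraries, with dotted lines at 2.6% and 3%. The wild-type libraries peak near 3.45% and 3.25%, and most knockout cells lie below 2.6%.

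From day 0 to day 6, wild-type cells showed a lower level of most pluripotency genes and a higher level of FOXA2 and of most hypoxia-response, glycolysis and matrix genes. TDGF1 (chromosome 3, 46574534 to 46582463) was 86.9-fold (74.3 to 102) lower at day 6, and POU5F1 4.54-fold (4.44 to 4.64). FOXA2, a transcription factor gene of floor plate and endoderm (chromosome 20, 22581005 to 22585455), was 24.5-fold (21.7 to 27.8) higher, at 91.8 CPM, and SP5, a WNT target, 31.3-fold (26.7 to 36.8). By the size rule 554 genes were higher and 1815 lower of 9319 measured. Of these genes 23.4% were higher, against 50.9% with TMM factors, and the median log2 ratio of all genes was -0.34, or 0.02 with those factors. List medians between days are again relative to all genes.

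The highest ratios in wild type included those of ANKRD1 (609-fold), ANXA1 (130.0-fold), EDN1 (79.7-fold), the imprinted RNA HYMAI (66.4-fold), EMP1 (62.7-fold), the nuclear receptor NR2F2 (48.9-fold), KCNJ2 (33.3-fold) and LGI1 (32.8-fold). The lowest included those of FOXD3-AS1 (919-fold lower), C9orf135 (54.3-fold), chromogranin CHGA (52.7-fold), VSNL1 (39.6-fold), GPR176 (34.5-fold), MAP7 (33.9-fold), the epithelial splicing factor ESRP1 (33.8-fold) and C6orf132 (24.7-fold), beside TDGF1. With the ambient profile subtracted, the log2 ratio was 10.17 against 9.23 for ANKRD1 and 6.14 against 5.04 for KCNJ2, and no day 6 counts of FOXD3-AS1 were left. With every cell weighted equally that of NR2F2 was 4.93 against 5.60. SIRT1 itself was 1.07-fold (1.00 to 1.14) lower at day 6 when scaled to total UMIs. Its log2 ratio of -0.09 lay above the -0.34 of all genes, so its direction rests on the scaling.

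Of the pluripotency list in wild type, 1 of 17 measured members were higher, 16 lower and 0 neither, the higher one being SOX2, also a gene of neural progenitors, at 1.67-fold. The list lay -1.35 from all genes, with DNMT3B 17.8-fold and L1TD1 10.6-fold lower. Of the hypoxia-response list, 12 of 14 measured members were higher, 0 lower and 2 neither, at 1.79 and percentile 100, with NDRG1 25.1-fold and P4HA1 4.71-fold higher. Of glycolysis genes, 17 of 24 measured members were higher, 2 lower and 5 neither, at 1.26, with SLC16A3 8.73-fold and LDHA 5.91-fold higher. Of the extracellular matrix and adhesion list, 14 of 21 measured members were higher, 2 lower and 5 neither, at 1.497, with FN1 12.7-fold higher and E-cadherin (CDH1) 13.7-fold lower. The WNT response list had 5 higher, 2 lower and 3 neither of 10, at percentile 99.99, with DKK1 29.1-fold and NKD1 10.7-fold higher, and the immediate early list 8 higher, 0 lower and 3 neither of 11, with JUN 22.9-fold higher. For cholesterol synthesis the counts were 12 higher, 2 lower and 7 neither of 21. Of the mitochondrially encoded genes, 0 of 13 measured members were higher, 10 lower and 3 neither, at -1.11, with MT-ND3 5.56-fold lower, and of the S phase list, 0 of 39 measured members were higher, 28 lower and 11 neither, at -0.84, with PCNA 4.28-fold lower. Of p53 targets, 7 of 22 measured members were higher, 2 lower and 13 neither, with PLK2 8.74-fold and CDKN1A 6.45-fold higher. With TMM factors 12 of the p53 targets were higher.

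In the knockout, day 6 against day 0 showed a higher level of FOXA2 and a lower level of most pluripotency genes. Across 9006 genes the log2 ratios of the 2 genotypes had Pearson's r of 0.852 and rho of 0.822, and 321 genes were higher and 649 lower in both, against 24.8 and 145 for independent lists. By the size rule 538 genes were higher and 801 lower of 9370 measured, 40.2% of them higher, against 51.8% with median-of-ratios factors. FOXA2 had the highest ratio, 102-fold (81.2 to 131), at 101 CPM against 0.988. HYMAI (68.6-fold), ANKRD1 (59.8-fold), the WNT inhibitor DKK1 (57.6-fold), LGI1 (54.1-fold), the axon guidance gene SLIT2 (41.6-fold), FOXB1 (30.3-fold), the collagen gene COL2A1 (24.9-fold), BMP4 (24.2-fold) and IGFBP5 (20.3-fold) followed. The lowest were FOXD3-AS1 (248-fold lower), TDGF1 (200.5-fold), ESRP1 (86.8-fold), C9orf135 (63.8-fold), CLDN7 (62.7-fold), B3GNT7 (57.6-fold), LCK (50.7-fold), SCGB3A2 (45.6-fold), the sodium channel gene SCNN1A (41.0-fold) and CDH1 (38.3-fold). The log2 ratios with the ambient profile subtracted were 6.92 against 5.83 for DKK1, 5.58 against 4.59 for BMP4, -9.10 against -7.91 for FOXD3-AS1 and -6.86 against -5.34 for SCNN1A. They were also further from 0 for TDGF1 (-8.41 against -7.63), CDH1 (-5.99 against -5.25) and SCGB3A2 (-6.09 against -5.49), and no day 6 counts of CLDN7 were left. In the knockout cells with a chromosome 20 share like wild type, the log2 ratios were -6.33 for TDGF1, -5.52 against -6.42 for ESRP1, -4.42 for SCGB3A2, -4.57 for SCNN1A, -4.43 for CDH1, 5.28 against 5.89 for ANKRD1 and 5.31 for BMP4.

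In the knockout pluripotency list, 1 of 17 measured members were higher, 13 lower and 3 neither, at -1.79 relative to all genes. The hypoxia-response list had 12 higher, 0 lower and 2 neither of 14, glycolysis 11 higher, 1 lower and 12 neither of 24, cholesterol synthesis 11 higher, 1 lower and 10 neither of 22, WNT response 5 higher, 1 lower and 3 neither of 9 and extracellular matrix and adhesion 13 higher, 1 lower and 7 neither of 21. The S phase list had 2 higher, 11 lower and 25 neither of 38, and the p53 targets 2 higher, 6 lower and 14 neither of 22, where CDKN1A had a ratio of 1.06. SPP1 was 2.42-fold lower at day 6 in the knockout, whereas it was 6.46-fold higher in wild type.

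Single cells showed where the stage markers stood. Thinned to 5000 UMIs, POU5F1 was found in 97.0% of wild-type and 98.2% of knockout cells at day 0, and in 41.9% (40.6 to 43.3) and 36.7% (35.2 to 38.1) at day 6, where free RNA at 10% would give 9.27% and 9.20%. NANOG was found in 12.0% and 4.80% at day 6 (free RNA 1.36% and 0.627%), after 20.7% and 18.9% at day 0. FOXA2 was found in 28.6% (27.4 to 29.9) and 30.5% (29.2 to 31.9) at day 6, where free RNA would give 3.92% and 4.57%, against 1.62% and 0.363% at day 0. The day 6 share in the knockout pools classes that differed, since FOXA2, on chromosome 20, stood at 183 CPM in knockout cells with a chromosome 20 share of 3% or more and at 63.0 CPM in those below 2.6%, against 91.8 CPM in wild type. Part of that gap comes with setting the classes by their chromosome 20 share. OTX2 was found in 15.8% and 19.97% at day 0 and 7.38% and 6.29% at day 6 (free RNA 0.757% and 0.726%). LMX1A, a marker of dopaminergic progenitors, was found in 0.258% of wild-type and 1.35% (1.03 to 1.74) of knockout cells at day 6, where free RNA would give 0.0584% and 0.126%, and SOX1 in 0.218% and 0.597% (free RNA 0% and 0.0503%). PAX6 was found in 0.0595% (0.0123 to 0.174) of wild-type cells, an interval that holds the 0.0584% of free RNA, and in 0.230% (0.110 to 0.422) of knockout cells (free RNA 0.101%). Thinned to 3000 UMIs the wild-type share was 0.109% (0.0399 to 0.236) against 0.0351% for free RNA. Whether the wild-type share is background thus stays open. TBXT was found in 0 of 5040 wild-type cells, which allows a share of cells with a UMI at this depth of up to 0.0595%, and in 0.0459% of knockout cells, and SOX17 was found in 0 of 4357 knockout cells, which allows a share with a UMI of up to 0.0689%. The neuronal gene STMN2 was found in 0.899% and 3.54% at day 0 (free RNA 0.178% and 0.187%). At day 6 it was found in 0.119% (0.0437 to 0.259) of wild-type cells, an interval that holds the 0.0876% of free RNA, and in 0.505% (0.317 to 0.763) of knockout cells (free RNA 0.0754%). Without thinning, day 6 shares, wild type first, were 51.5% and 55.02% for POU5F1, 38.8% and 48.1% for FOXA2 and 0.538% and 3.27% for LMX1A. Thinning left out 203 and 489 cells at day 0 and 540 and 72 at day 6.

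Phase scores on thinned cells placed 0.826% of wild-type and 2.001% of knockout cells in G1 at day 0, and 32.5% and 23.4% at day 6. The S phase shares were 42.0% and 44.1% at day 0, and 20.4% and 27.6% at day 6. Summed levels of the S phase list were 3404 and 3193 CPM at day 0 and 1617 and 2485 CPM at day 6. Without thinning the G1 shares were 0.743% and 1.90% at day 0, and 36.8% and 21.5% at day 6, and the S phase shares 43.3% and 38.6% at day 0, and 22.5% and 35.0% at day 6. The order of the S phase shares at day 0 thus turned with thinning, and none is read from them. Phase scores also read free RNA, whose part in these shares stays open, and no cycling is read from phase calls alone.

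Clustered by itself, each day 0 library was mostly pluripotent-like. In wild type a cluster of 232 cells was neural progenitor-like, led by IGFBP5, PTN and DLK1, and 81 cells led by NTS, HOXB-AS3 and LHX1 stayed unnamed, with 4 markers each of the mesoderm and mesendoderm sets. In the knockout a pluripotent-like cluster of 1898 cells was led by SLC16A3, ANKRD37 and APLN, and a cluster led by FN1, COL1A1 and IGFBP5 stayed unnamed, with 5 neural progenitor markers (SOX1, HES5, FABP7, LHX2 and LHX5) and 3 neural crest markers up. At day 6, a cluster of 982 wild-type and one of 990 knockout cells were pluripotent-like, with POU5F1 and ESRG among their leading genes. In both, the name rests on 4 fixed markers that were higher than in the library's other cells: POU5F1, NANOG, DPPA4 and L1TD1. The fixed marker TDGF1 was not among these. Its level over the whole day 6 libraries was 2.99 CPM in wild type and 0.857 CPM in the knockout. The name therefore does not show that these cells had stayed undifferentiated. FN1, LINC00261 and FOXA2 were among the leading genes of clusters of 1201 and 180 wild-type and 822 knockout cells, all with too few fixed markers for a name. Cluster sizes were not compared between libraries, since the genes that define clusters differed between them.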

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

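In this part, the tests of the p53 pattern, between like clusters and in the knockout cells with a chromosome 20 share like wild type, were chosen only after the result was seen, and no difference between effects was itself tested, since each group had 1 library. Each gene is listed because it passed the size rule in opposite directions at the days or in the genotypes compared. Each gene list stands here because its medians lay outside those of random lists, on opposite sides of 0. Genes that changed sign without passing the size rule in both directions are not listed. Values are log2 ratios scaled to total UMIs.

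For the following, knockout against wild type had opposite signs at the 2 days. APLN lay at 2.36 at day 0 and -1.33 at day 6, a difference of -3.70. FN1 lay at 1.49 and -1.39, a difference of -2.88, and at day 0 its ratio was 0.27 within pluripotent-like clusters. At day 6 FN1 stood at 145 CPM in knockout cells with a chromosome 20 share like wild type and 39.9 CPM in those below 2.6%, against 204 in wild type. The long non-coding RNA AP000459.2, which the rule for named genes leaves out by its name, lay at -1.54 and 1.04, a difference of 2.58. Its day 6 level was 33.3 CPM in knockout cells with a share like wild type, close to the 33.6 of wild type, and 86.6 in those below 2.6%, so the higher day 6 value was not seen in the former class. The median of the list of neuronal genes was 0.23 at day 0 and -0.50 at day 6, a difference of -0.73, over 6 measured members at day 0 and 4 at day 6, so not over the same genes, and 0.032 and -0.25 in knockout cells with a share like wild type. The median of the S phase list was -0.13 and 0.59, a difference of 0.72, over 39 and 37 members.

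For the next, day 6 against day 0 had opposite signs in the 2 genotypes. SPP1 lay at 2.69 in wild type and -1.27 in the knockout, a difference of -3.96, and FOSL1 at 1.37 and -1.60, a difference of -2.96. APLN lay at 1.10 and -2.60, which gives the same -3.70 as its difference between days.

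The median of p53 target genes in knockout against wild type was 0.29 at day 0 and -0.52 at day 6 (difference -0.81), and that of day 6 against day 0 was 0.37 in wild type and -0.34 in the knockout (difference -0.71), where the knockout value lay at percentile 2.09 of random lists, inside their central 95% with the UMI limit doubled (percentile 2.8) or a minimum of 5 CPM (2.54), and was -0.16 at percentile 39.05 at a minimum of 50 CPM. The chromosome 20 difference as the whole cause of the lower day 6 value is argued against by -0.42 in knockout cells with a chromosome 20 share like wild type. The list median was -0.32 between pluripotent-like clusters (990 knockout and 982 wild-type cells), at percentile 0 of random lists. It was -0.92 between clusters with FOXA2 among their leading genes (822 and 1381 cells), also at percentile 0. Different shares of these clusters alone are thus argued against as the whole cause, although other states were not compared. Each library was clustered by itself and the second pair was matched by FOXA2 alone, so differing states within a pair stay open. SIRT1 is known to deacetylate p53, but the list lay above 0 at day 0 and below 0 at day 6. That link alone therefore does not give the lower day 6 direction, and the SIRT1 genotype stays an open and untested hypothesis. Equally open and untested are differences between the single cultures of each genotype, such as density or handling at dissociation, which the immediate early genes may also reflect.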

How the results depend on the processing

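The tests based on chromosome 20 (knockout cells with a share like wild type, as many knockout cells drawn at random, and leaving out chromosome 20 genes) and the counts of list members and of genes that differed between days under alternatives were chosen only after the results were seen. All other alternatives were chosen before the data were examined. No paired analysis was possible because the labels give no replicate numbers that the groups share, each group having 1 library, and no library was left out in turn. The comparison of pluripotent-like clusters was not run for day 6, where no class covered the library, nor for the correlation and counts between days, which need both days. Counts set to a minimum CPM or another fold differ by construction, since other genes enter. For every other result that moved, the cause was not tested. Genes under 10 CPM in both libraries were not compared, and no alternative gives a spread between cultures.

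As reported, 40 genes were higher and 43 lower in the knockout at day 0, 270 and 173 at day 6, 554 and 1815 at day 6 against day 0 in wild type and 538 and 801 in the knockout. The SIRT1 ratio was 0.220 at day 0 and 0.329 at day 6, the correlation between days 0.232, and 291 genes had a more positive and 109 a more negative knockout ratio at day 6. These counts, ratios and the correlation, where run, stayed within 1.5 times or within their intervals with the UMI limit doubled or fixed at 5000, a mitochondrial limit of 10% or none, the highest doublet scores removed and pluripotent-like clusters alone. SIRT1 stayed lower in the knockout at both days under each alternative run for it.

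With every cell weighted equally, the SIRT1 ratio at day 6 was 0.367 and the correlation 0.269. With the free RNA profile subtracted, the SIRT1 ratio at day 0 was 0.191 and the correlation 0.341. TMM factors gave 100 higher and 283 lower at day 6, a SIRT1 ratio of 0.280 there, and 1002 and 965 between days in wild type. Median-of-ratios factors gave 98 and 286, 0.279, and 1164 and 771. Totals without mitochondrial and ribosomal protein genes gave 262 lower at day 6. Genes with a more positive and a more negative ratio at day 6 numbered 95 and 170 with TMM, 67 and 214 with median-of-ratios, 264 and 165 with those totals, 482 and 172 at 5 CPM and 44 and 23 at 50 CPM. The share of higher genes was 60.9% at day 6 as reported, 26.1% with TMM, 25.5% with median-of-ratios and 46.6% with those reduced totals. Between days it was 23.4%, 50.9% and 60.2% in wild type and 40.2%, 49.7% and 51.8% in the knockout, for the total, TMM and median-of-ratios. In that order the median log2 ratio of all genes was 0.25, 0.01 and 0.00 at day 6, -0.34, 0.02 and 0.12 between days in wild type and -0.09, 0.01 and 0.03 in the knockout.

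At a minimum of 5 CPM the counts were 61 and 80 at day 0 and 410 and 262 at day 6, and the correlation 0.299. At 50 CPM they were 8 and 10, 48 and 62, and between days 236 and 527 in wild type and 212 and 227 in the knockout, with a correlation of 0.186. At 1.5-fold the same 4 pairs were 136 and 184, 1513 and 377, 1098 and 3464, and 1291 and 1957. At 4-fold they were 4 and 14, 16 and 45, 175 and 301, and 140 and 194.

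In knockout cells with a chromosome 20 share like wild type, 24 genes were higher at day 0, the SIRT1 ratio was 0.243 and the correlation 0.0892. As many cells drawn at random gave a day 0 SIRT1 ratio of 0.186, and leaving out chromosome 20 genes a correlation of 0.210. Some values crossed 0. In the cells with a share like wild type, the integrated stress response list at day 0 was at 0.10, TRIB3 at 0.023 and the 20q11.21 list at day 6 at 0.37 (all genes 0.25). That choice of cells by itself raises genes of chromosome 20, which enter each of these values. Without chromosome 20 genes the endoderm list between days in the knockout, which then lacks FOXA2, was at -1.07. Relative to all genes, the next 3 kept their side. Without chromosome 20 genes the BMP response list at day 6 was at 0.11, with all genes at 0.26. In wild type between days, nuclear oxidative phosphorylation genes were at 0.048 with median-of-ratios factors, with all genes at 0.12, and neural progenitor genes at -0.10 at 5 CPM, with all genes at -0.38.

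Of 2515 list medians under an alternative, 2374 stayed within their range, 135 moved out of it and 6 were counted as crossing 0. For named genes these were 5642, 1431 and 1 of 7074. A crossing was counted only for lists that lay outside random lists, and genes at least 1.5-fold apart, as reported. Other changes of sign are among the values that stayed or moved. Of 88 shares of cells, 57 moved with another thinning, of 12 phase shares 8 without thinning, and of 8 cluster numbers 4 with the resolution. With TMM factors the count of members past 1.5-fold, higher or lower, moved by over 1.5 times in 0 of 39 lists in knockout against wild type at day 0 and 25 of 41 at day 6, and between days in 23 of 40 in wild type and 12 of 41 in the knockout. In knockout cells with a chromosome 20 share like wild type it did so in 16 at day 0 and 21 at day 6.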

Other observations

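In this part, the chromosome arm test was chosen before its result was seen, and the other tests of the chromosome 20 and hypoxia patterns only after. Gene groups not yet described are given first, as values without explanation, with medians relative to all genes.

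In undifferentiated cells, knockout against wild type, several signalling and lineage lists showed few members past 1.5-fold. Of the naive and primed state list, 0 of 6 measured members were higher, 0 lower and 6 neither, with a median of 0.32 at percentile 99.95, and of the Notch response list 0 of 7 measured members were higher, 0 lower and 7 neither, at 0.29 and percentile 99.89. The first median was 0.046 in knockout cells with a chromosome 20 share like wild type, and the second 0.11 with totals that left out mitochondrial and ribosomal protein genes. Those totals hardly moved the median of all genes but raised the measured genes from 9093 to 10249. The lower value thus goes with other members being measured, not with the scaling itself. Neuronal genes had 0 higher, 0 lower and 6 neither of 6, the FGF and ERK response 1 higher, 0 lower and 12 neither of 13 with DUSP4 higher, and NF-kappa-B and interferon genes 0 higher, 0 lower and 8 neither of 8. In the retinoic acid response list CYP26A1, which breaks retinoic acid down (2.19-fold), and CRABP1 (1.51-fold) were higher and DHRS3 was 2.18-fold lower. The BMP response list had ID2 higher and ID1, on chromosome 20, lower of 4 members, the NODAL and TGF-beta response list TDGF1 lower of 5, the mesoderm list COL1A2 lower of 4 and the endoderm list APOA1 higher of 2. The log2 ratio of APOA1 was 1.97, and 3.38 in as many knockout cells drawn at random as had a chromosome 20 share like wild type. A random draw would not move it this far if the counts were spread evenly over cells. Much of its count thus lay in few cells, and its ratio rests on them. APOA1 also led a cluster of 88 knockout cells with a median of 24375.5 UMIs, against 8309 over the library. Of antioxidant and NRF2 target genes, 0 of 21 measured members were higher, 3 lower and 18 neither, with SRXN1 (on chromosome 20) 1.66-fold, the cystine transporter SLC7A11 1.65-fold and heme oxygenase HMOX1 1.92-fold lower. Sirtuins and NAD metabolism had 0 higher, 2 lower and 7 neither of 9, with NAPRT 1.58-fold lower beside SIRT1. None of the measured members of the TCA cycle (24), mitochondrial biogenesis (14), fatty acid oxidation (16), sphingolipid (9) and unfolded protein response (12) lists passed 1.5-fold.

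At day 6, the tricarboxylic acid cycle list had 4 higher, 0 lower and 19 neither of 23 in knockout against wild type, with the isocitrate dehydrogenases IDH1 (1.65-fold) and IDH2 (1.52-fold) higher. Histone modifiers and DNA methylation genes had 4 higher, 0 lower and 17 neither of 21, at 0.19 and percentile 98.73, with the demethylating enzyme TET1 1.84-fold and UHRF1 1.71-fold higher. The naive and primed state list had 3 higher, 0 lower and 3 neither of 6, with ZIC2 1.83-fold higher, and the FGF and ERK response 4 higher, 3 lower and 6 neither of 13, with ETV1 1.58-fold higher and FOSL1 5.66-fold lower. Of the NODAL and TGF-beta response, 1 of 4 measured members were higher, 2 lower and 1 neither, at -0.84, or -0.45 without chromosome 20 genes, with PMEPA1, on chromosome 20, 1.996-fold lower. The BMP response list had 1 higher, 2 lower and 2 neither of 5, with ID4 1.73-fold lower and ID3 1.695-fold higher. Of the mesoderm list, 1 of 6 measured members were higher, 3 lower and 2 neither, with KDR 2.64-fold higher and BMP4 at a log2 ratio of -1.24, or -0.0042 in knockout cells with a chromosome 20 share like wild type. Neuronal genes had 1 higher, 2 lower and 1 neither of 4, with INA 1.58-fold lower, and antioxidant genes 0 higher, 3 lower and 17 neither of 20, at -0.34, with NQO1 2.07-fold lower. With TMM factors the tricarboxylic acid cycle list had 0 higher and 1 lower, the histone and DNA methylation list 2 higher and the antioxidant list 6 lower.

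The remaining lists at day 6 held few measured members or few past 1.5-fold. PAX8 was 14.4-fold higher in the floor plate and placode lists, and CRYAB was 19.8-fold lower in the latter. The hedgehog receptor gene PTCH1 was 3.01-fold higher, SIX6 of the anterior forebrain list 8.18-fold, CXCR4 of the endoderm list 1.67-fold, IGFBP3 of the amnion and trophoblast list 1.94-fold and CRABP1 of the retinoic acid list 1.78-fold. In the knockout cells with a chromosome 20 share like wild type the log2 ratio was 1.56 against 0.95 for IGFBP3 and 0.11 against 0.83 for CRABP1, while the hindbrain and spinal cord list held GBX2 alone. No gene of the primitive streak and mesendoderm list was measured in any comparison. Counts were 3 higher, 1 lower and 15 neither of 19 for serine, one-carbon and amino acid metabolism, 1 higher, 2 lower and 12 neither of 15 for autophagy and lysosome, 0 higher, 2 lower and 7 neither of 9 for heat shock and 1 higher, 1 lower and 10 neither of 12 for the unfolded protein response, with HSPA5 2.14-fold lower. They were 1 higher, 0 lower and 14 neither of 15 for fatty acid oxidation, 1 higher, 0 lower and 9 neither of 10 for mitochondrial biogenesis, 0 higher, 0 lower and 8 neither of 8 for sphingolipids, 0 higher, 1 lower and 7 neither of 8 for sirtuins and NAD metabolism, 0 higher, 1 lower and 7 neither of 8 for the Notch response and 1 higher, 1 lower and 5 neither of 7 for NF-kappa-B and interferon. Between days, the naive and primed list had 1 higher, 5 lower and 0 neither of 6 in wild type and 1 higher, 5 lower and 0 neither of 6 in the knockout, and neuronal genes 2 higher, 5 lower and 0 neither of 7 and 0 higher, 4 lower and 2 neither of 6.

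Genes of chromosome 20 were lower in the knockout at both days, so that most knockout cells differed from wild type in both the SIRT1 genotype and the chromosome 20 share. A gained or lost chromosome arm in 1 of the 2 lines is in line with the values, since the smaller deviation of 20p was -0.34, past a bound of 0.3 set before for at least 1 arm though its interval (-0.41 to -0.25) held that bound, with 20q at -0.28 at day 0 and -0.39 at day 6, while the tables argue against wild-type cells mixed into the knockout libraries (SIRT1 ratio of 0.310 in the cells with a share like wild type, the higher day) and against counting error as the source of the classes of cells (correlation of 0.616 between the shares of the chromosome's parts, the lower day). In cells below 2.6% the median log2 ratio of chromosome 20 genes was -0.53 at day 0 and -0.59 at day 6 (intervals -0.57 to -0.51 and -0.64 to -0.56), where 2 copies against 3 give -0.58, 3 against 4 -0.42 and 1 against 2 -1. The day 6 interval held the first of these and the day 0 interval none, and picking cells on a low share moves the value down, so the copy numbers, and how the classes arose, stay open. A candidate explanation is that most knockout cells carried fewer copies of chromosome 20 than most wild-type cells and the minor class, which no DNA measurement was used here to test.

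The classes also differed in genes of other chromosomes. Between cells at 3% or more and cells below 2.6%, 17 genes were at least 2-fold higher and 16 lower at day 0, and 59 and 49 at day 6, of which 4 and 13 of the higher ones lay on chromosome 20. No random split of the cells was counted for comparison, and at day 6 the classes also differed in their clusters. APOA1, among the higher genes at day 0, had a log2 ratio to wild type of 3.42 in the cells at 3% or more. In as many cells drawn at random it was 3.38.

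Hypoxia-response genes were higher in the knockout at day 0, with a list median of 0.69. The chromosome 20 difference is argued against by a median of 0.70 in knockout cells with a share like wild type. The cluster led by SLC16A3, ANKRD37 and APLN as the whole source is argued against by 0.41 in the 5486 knockout cells outside it, above random lists (-0.12 to 0.14), though below the value over all cells. Lower oxygen or denser growth in the single knockout culture may account for it and was not tested. The SIRT1 genotype stays open as a hypothesis, since SIRT1 is known to act on hypoxia-inducible factors.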
